A study of Mus musculus with 8 samples.

How the data were processed

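RNA of single nuclei was measured by inDrops, a droplet method in which each transcript receives a unique molecular identifier (UMI). Per the labels, the nuclei came from visual cortex of 10-week mice on the C57BL/6 background that had spent 1 week in the dark, and they were captured by antibody through a GFP-tagged protein of the nuclear envelope. The mice carried either a conditional knockout of Dnmt3a or a knockout of Mecp2, and each knockout had wild-type littermates as its control. The 8 samples of the series are sequencing runs of mixed libraries, so the labels place 0 of them in a genotype group. A list of barcodes gives 3 wild-type and 3 knockout libraries for Dnmt3a and 6 and 6 for Mecp2, and it does not name cell types. Each genotype was spread over 2 pairs of runs, and the Dnmt3a and Mecp2 libraries shared no run.

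The submitters' processing notes name Trimmomatic 0.33, Bowtie 1.1.1 and Seurat (version not given) and the genome builds GRCm38.p5 and mm10, without saying what each was used for. The authors' tables hold 8 columns, per the file headers 1 for each knockout, genotype and cell type (Pv or Vip), and 25289 genes. How the values were made is not stated. From the values, the unit of the deposited columns is UMI per 10000, that is, the mean over nuclei of each nucleus's UMI counts scaled to a total of 10000. Each column sums to 10000, and the values of genes seen in a single nucleus equal 10000 divided by a whole number of nuclei and by a whole nucleus total. The sources used here do not say how doublets (2 nuclei in 1 droplet) were treated before the means were taken, and pooled means allow no correction for them. No values per library, animal or nucleus were analysed here.

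The number of nuclei in each column and their UMI totals were recovered from those smallest values, counting a total as whole within 0.02 and requiring at least 3 repeats of a value and a share of 80% whole totals, where chance gives 4%. The lowest nucleus total accepted was 500. Levels were turned into UMI equivalents by the value of 1 UMI in that column. Exact Poisson (Garwood) 95% intervals were taken for levels and exact binomial (Clopper-Pearson) 95% intervals for ratios. These intervals cover counting error only and say nothing of the spread between nuclei or animals. The recovery and the intervals were tested on simulated data of the same size, in which all nuclei of a pool shared a single expression profile. The simulation could not show how the intervals do where nuclei of a pool differ. The number of nuclei was exact in 8 of 8 columns, the mean nucleus total was within 1.2%, and the intervals held the true ratio for 94.1% to 96.0% of genes. A 2-fold difference was simulated in 200 genes, all picked above the level limit for measured genes given below. Of those measured, 99.5% to 100% passed the size rule given below, as did 1.3% to 2.7% of the genes simulated without a difference.

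The measure was the log2 ratio of the knockout mean to the wild-type mean, with no pseudocount. Since the tables give a single pooled value per genotype and cell type, no test between animals could be made, and no p-value is given. The plan fixed before the data were examined had foreseen this case as ratios without a test, so a size rule took the place of a p threshold: a gene was called higher or lower when its log2 ratio was at least 0.5 in size (1.41-fold). Only measured genes were called, meaning genes whose mean level kept the counting spread of the log2 ratio within 0.25. That level was set after the unit was known. The planned filter, genes above the median level, reaches down to medians near 0.03 UMI per 10000 and was kept as an alternative. The count that counting error alone would give was taken from 200 draws without a difference.

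There were 4 comparisons, knockout against its own wild type in Pv and in Vip nuclei. For each, 22 gene lists fixed before the data were examined were described by the number of members past the size rule and by the median log2 ratio. The percentile of that median came from 10000 random lists of the same size, matched on mean level in 20 bins, and was given for lists with at least 3 measured members. A median below percentile 2.5 or above percentile 97.5 is described as outside the range of random lists. These percentiles describe the pools and are not tests across animals. The lists cover DNA methylation machinery, MeCP2 partners, markers of PV, VIP, SST and LAMP5 interneurons, pan-GABAergic genes, markers of excitatory neurons, astrocytes, oligodendrocytes, and microglia and vessels, immediate-early genes, glutamate receptors, GABA receptors, voltage-gated channels, adhesion and guidance genes, neuropeptides, imprinted genes, germline genes, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain and mitochondrially encoded genes. Haemoglobin, Y-linked genes, X-linked genes that escape inactivation, and X inactivation transcripts were added after the data were seen.

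Agreement between knockouts and between cell types was described by Spearman's rho and Pearson's r across genes and by the number of genes past the size rule in both, beside the number that independence would give. Genes are not independent replicates. Gene length came from the GENCODE M21 annotation of GRCm38, which held 24535 (97.0%) of the gene symbols. Another 26 symbols had been turned into calendar dates in the deposited tables, and 2 of these were listed in duplicate.

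Genes were named by a rule set before the data were examined, with some of its terms replaced. The size rule took the place of its p threshold, and the limit for measured genes, set later, that of its level filter. Named were, per comparison, the 8 measured genes with the largest ratio in each direction past the size rule, up to 6 genes per direction shared by both cell types and up to 6 shared by both knockouts, the targeted gene, and members of the fixed lists. With no p-values, shared genes were ranked by the smaller of their ratios instead. The first parts of the rule gave 28, 24, 26 and 23 genes for Dnmt3a Pv, Dnmt3a Vip, Mecp2 Pv and Mecp2 Vip, and 66 in all. Any other gene named was chosen after its values were seen.

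Alternatives changed the level filter, the pseudocount (0.1 UMI per 10000), the size rule (log2 ratio of 1), the counting spread (0.15), the centring, the matching and summary of lists, the members of lists (without the targeted gene), and the set of genes. Planned thresholds on p-values, replicates left out in turn and fits of a count model were left out because they need p-values or values per library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.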

Results

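Nuclei called Pv or Vip, after the interneuron markers parvalbumin and vasoactive intestinal peptide, were compared between knockout and wild-type mice for Dnmt3a, which encodes a DNA methyltransferase, and for Mecp2, which encodes a protein that binds methylated DNA. The series title places the work in the question of how early gene expression shapes lasting epigenetic states in neurons. For Dnmt3a, the authors' means pooled 831 wild-type and 793 knockout Pv nuclei and 330 wild-type and 378 knockout Vip nuclei. For Mecp2, they pooled 775 wild-type and 711 knockout Pv nuclei and 480 wild-type and 439 knockout Vip nuclei. Mean depth per nucleus lay between 958.2 and 1193 UMI, and the pools held 955167, 945824, 316202 and 410086 UMI for Dnmt3a (wild-type Pv, knockout Pv, wild-type Vip, knockout Vip) and 909948, 805918, 492233 and 432585 for Mecp2. At a counting spread of 0.25 in the log2 ratio, levels above 0.822 (Dnmt3a Pv), 2.29 (Dnmt3a Vip), 0.955 (Mecp2 Pv) and 1.72 (Mecp2 Vip) UMI per 10000 were measured, which gave 3046, 843, 2648 and 1272 genes. A list of barcodes gives 3 and 3 libraries for Dnmt3a and 6 and 6 for Mecp2, but the tables hold a single pooled mean per genotype and cell type, so no replicate values were analysed, and all intervals given are 95% counting intervals. Coordinates are on GRCm38.

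The pools carried the markers of their names, but not those alone. Pvalb stood at 5.50 UMI per 10000 in wild-type and 5.59 in knockout Pv nuclei of the Dnmt3a table and at 5.16 and 6.00 in those of the Mecp2 table, and did not exceed 0.171 in any Vip pool. Vip, in turn, was 85.8 and 91.6 in wild-type and knockout Vip nuclei of the Dnmt3a table, 53.6 and 42.6 in those of the Mecp2 table, and at most 0.111 in Pv nuclei. Gad1, the main GABA-synthesising enzyme, was between 14.9 and 25.3 in every pool. Genes listed here as markers of other interneurons were present too. Sst was 3.49 in wild-type Pv nuclei of the Dnmt3a table and 1.64 in those of the Mecp2 table. In wild-type Vip nuclei of the Mecp2 table Npy was 20.8 and Lamp5 5.58, against 5.39 and 1.34 in those of the Dnmt3a table.

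The targeted genes came first. Mecp2 (chromosome X, 74026592 to 74135363) was lower in the Mecp2 knockout in both cell types: 1.80 UMI per 10000 in wild-type and 0.851 in knockout Pv nuclei, a log2 ratio of -1.08 (-1.56 to -0.62), and 2.47 and 0.916 in Vip nuclei, a log2 ratio of -1.43 (-2.04 to -0.85). In the Dnmt3a table Mecp2 had a log2 ratio of 0.14 (-0.22 to 0.50) in Pv nuclei. Dnmt3a in its own conditional knockout was 0.975 in wild-type and 0.887 in knockout Pv nuclei, a log2 ratio of -0.14 (-0.62 to 0.34), and 0.830 and 0.504 in Vip nuclei, a log2 ratio of -0.72 (-1.74 to 0.27). A difference in Dnmt3a was thus not detectable at this depth in either cell type. The labels do not say which part of either gene is deleted, and 3' tags from outside a deleted part check nothing.

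In Pv nuclei of the Dnmt3a knockout the largest differences lay in peptide-related genes and in mitochondrial transcripts. Crhbp, whose product binds corticotropin-releasing hormone (chromosome 13, 95431371 to 95444924), was 0.992 UMI per 10000 in wild type and 4.03 in the knockout, a log2 ratio of 2.02 (1.67 to 2.39). Npy, encoding neuropeptide Y (chromosome 6, 49822710 to 49829507), was 1.43 and 5.41, a log2 ratio of 1.92 (1.62 to 2.23). The 13 mitochondrially encoded genes summed to 47.0 in wild type and 22.7 in the knockout, a log2 ratio of -1.05 (-1.13 to -0.97). Of 3046 genes, 138 were higher and 156 lower past the size rule, where counting error alone gave 21.1 and 20.8; centred on the median ratio the split was 151 and 132 (46.9% higher, 53.4% when centred), so which direction held more genes depended on that shift.

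After Crhbp and Npy, the higher genes with the largest ratios were Cpne8, a calcium-dependent lipid-binding protein (log2 ratio 1.52), Lypd6, a modulator of nicotinic receptors (1.44), the secreted Dickkopf-family protein Dkk3 (1.09), the delayed-rectifier potassium channel gene Kcnb2 (1.07), Pithd1 (1.05) and Rev3l, a DNA polymerase subunit (1.03). The lower genes with the largest ratios were mt-Nd4 (-1.64), mt-Atp6 (-1.60), mt-Nd2 (-1.44), mt-Cytb (-1.35) and mt-Nd1 (-0.97) of the mitochondrial genome, the complex III subunit gene Uqcr11 (-1.03), the phosphodiesterase gene Gdpd1 (-1.01) and the nucleoside transporter gene Slc29a2 (-0.97).

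By list, 8 of 8 measured mitochondrially encoded genes were lower in Dnmt3a knockout Pv nuclei (median log2 ratio -1.16, -1.31 to -0.99, below all random lists). The nuclear-encoded respiratory chain went the same way, with 15 of 54 genes lower and 0 higher (median -0.29, percentile 0), among them Uqcr11 (-1.03), Cox6b1 (-0.96) and Ndufa5 (-0.87). Imprinted genes had positive ratios in 10 of 11 cases (median 0.35, 0.22 to 0.45, percentile 100), although only Inpp5f (0.52) passed the size rule. Meg3, a maternally expressed long noncoding RNA, was 65.0 in wild type and 91.7 in the knockout (0.50, just under the rule), and Rian, from the same imprinted cluster, 15.9 and 21.1 (0.40). The neuropeptide list, which also holds the binding-protein gene Crhbp, had 3 of 6 members higher, Crhbp, Npy and Sst (median 0.36, percentile 99.95). Its percentile without Crhbp was not taken. SST interneuron markers (median 0.36, percentile 99.5) had 2 of 4 higher, Npy and Sst. Sst was 3.49 in wild type and 5.06 in the knockout (0.54). Cytosolic ribosomal proteins had 46 of 69 ratios above 0 and none past the size rule (median 0.11, percentile 99.96). GABA receptors had 9 of 11 ratios below 0 and none past the rule (median -0.23, percentile 1.32); Gabra1, the most abundant, was 26.4 and 19.5 (-0.43). PV markers (median -0.04, percentile 45.1), DNA methylation machinery (-0.03, percentile 46.4), MeCP2 partners (0.08, percentile 69.4), pan-GABAergic genes (-0.08, percentile 29.5), glutamate receptors (0.02, percentile 70.5), adhesion and guidance genes (0.03, percentile 83.9) and voltage-gated channels (-0.12, percentile 3.31) stayed within the range of random lists. Among the channels, Kcnb2 (1.07) and Kcna6 (0.72) were higher and Kcnmb2 (-0.69), Kcnab2 (-0.66) and Kcnq3 (-0.61) lower.

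Transcripts that mark sex and other cell types also differed in these Pv pools. Xist, the X inactivation RNA of female cells, was 14.9 in wild type and 9.35 in the knockout, a log2 ratio of -0.67 (-0.80 to -0.54), and 4 Y-linked genes summed to 1.17 and 2.57, a log2 ratio of 1.13 (0.78 to 1.50). Summed astrocyte markers had a log2 ratio of 0.37 (0.18 to 0.56), excitatory neuron markers -0.20 (-0.30 to -0.10) and oligodendrocyte markers 0.08 (-0.09 to 0.24). Without mitochondrially encoded, haemoglobin, Y-linked and X inactivation genes, a set chosen after the data were seen, 138 genes were higher and 147 lower. The percentiles of the SST and GABA receptor lists and of neuropeptides moved within the range of random lists (88.3, 5.68 and 89.7) when members above the median level of all genes were used.

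**Figure D1:**
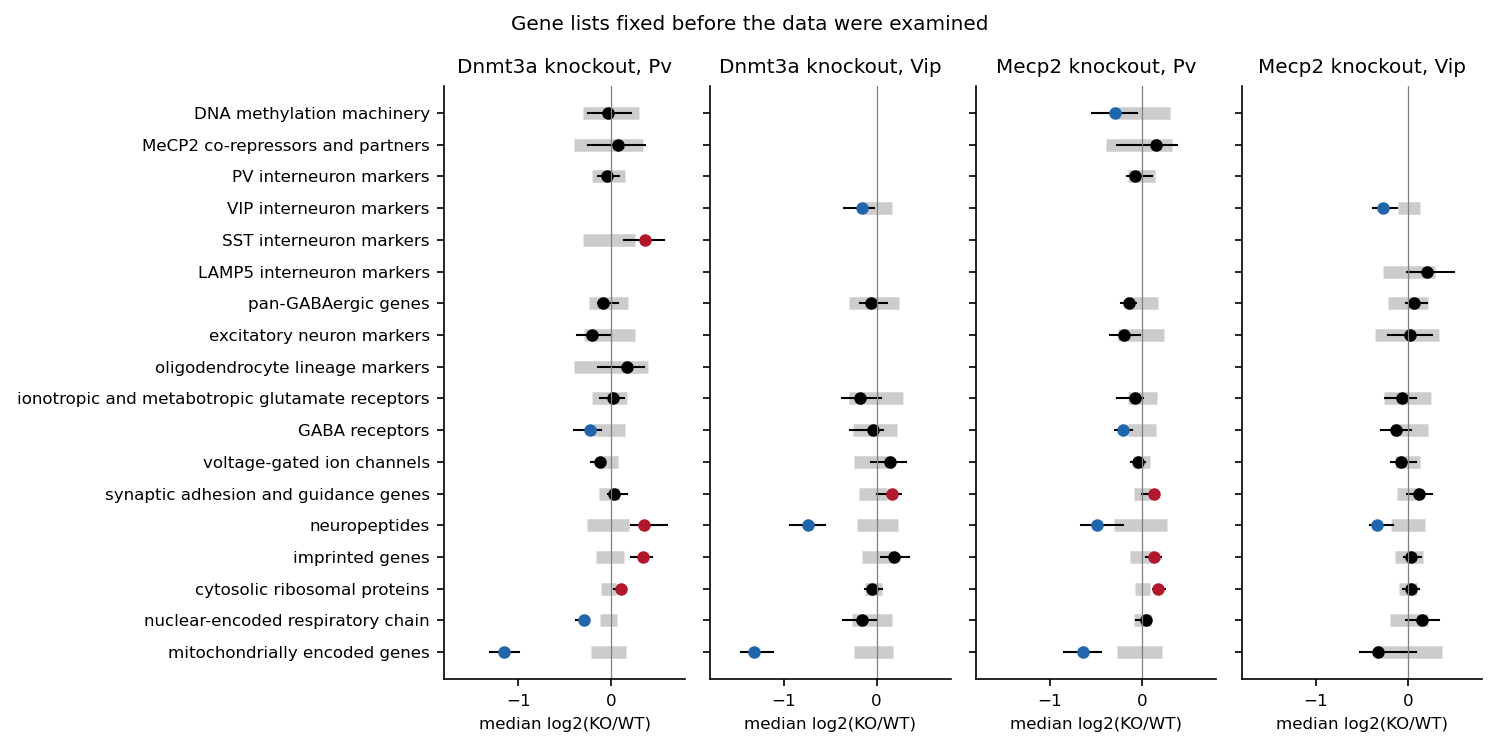
Median log2 ratio of knockout to wild type (x axis) for each fixed list with at least 3 measured members, in the 4 comparisons; points are medians, black lines their 95% counting intervals, grey bars the central 95% of 10000 random lists, red and blue points medians above and below it. Mitochondrially encoded genes sit at -1.16 and -1.32 in Pv and Vip nuclei of the Dnmt3a knockout, and neuropeptides at 0.36 and -0.74.

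In Vip nuclei of the Dnmt3a knockout, 4 of 6 measured neuropeptide genes were lower past the size rule, while Vip and Cck had positive ratios. Whether the mix of interneuron types among these nuclei differed between genotypes was not tested, so these differences need not lie within VIP cells. Tac2, the neurokinin B precursor (chromosome 10, 127724478 to 127731768), was 13.8 UMI per 10000 in wild type and 5.46 in the knockout, a log2 ratio of -1.34 (-1.61 to -1.08). Npy was 5.39 and 2.01, a log2 ratio of -1.42 (-1.86 to -0.99), opposite in sign to Pv nuclei. Penk, the enkephalin precursor, had a log2 ratio of -0.85 and Crh, corticotropin-releasing hormone, -0.63, whereas Vip itself was 85.8 and 91.6 (0.10). Mitochondrially encoded transcripts summed to 72.8 and 30.0, a log2 ratio of -1.28 (-1.39 to -1.17). Of 843 genes, 30 were higher and 51 lower past the size rule, where counting error alone gave 7.53 and 6.27; centred on the median ratio of -0.03, the split was 40 and 40, so the excess of lower genes (a share of 37.0% higher, 50% when centred) depended on that shift.

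The higher genes with the largest ratios in these Vip nuclei were Nrsn2, a neuronal vesicle protein (1.25), the adhesion genes Pcdh19 (1.23) and Slitrk4 (1.02), Rasgrf1, a Ras exchange factor that is imprinted in mouse and not on the fixed list (0.92), Arl8a, which moves lysosomes (0.90), B3galt2 (0.88), the deadenylase-related gene Noct (0.84) and the splicing factor gene Prpf19 (0.83). Apart from Npy and Tac2, the lower ones were mt-Atp6 (-1.75), mt-Nd2 (-1.56), mt-Nd4 (-1.48), mt-Cytb (-1.45), mt-Nd1 (-1.20) and the phospholipid phosphatase-related gene Plppr5 (-1.19).

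Of 11 lists with enough measured members in Dnmt3a Vip nuclei, 4 lay outside the range of random lists. Neuropeptides had 4 of 6 members lower (Npy, Tac2, Penk, Crh; median -0.74, -0.94 to -0.55, percentile 0.005), and VIP markers 3 of 12 (Tac2, Penk, Crh; median -0.15, percentile 2.02), while Cck (0.40), Htr3a (0.40) and Cnr1 (0.27) had positive ratios. Mitochondrially encoded genes were lower in 8 of 8 cases (median -1.32, percentile 0). Adhesion and guidance genes had 3 of 19 members higher, Slitrk4 (1.02), Lsamp (0.78) and Epha5 (0.51), and 0 lower (median 0.17, percentile 99.7). Imprinted genes (0.19, percentile 96.2), the nuclear-encoded respiratory chain (10 genes, -0.15, percentile 17.8), ribosomal proteins (-0.05, percentile 42.8), pan-GABAergic genes (-0.06, percentile 33.1), glutamate receptors (-0.17, percentile 10.6), GABA receptors (-0.04, percentile 37.6) and voltage-gated channels (0.15, percentile 95.0) stayed within it, with Ndn (0.64) and Meg3 (0.48) the imprinted genes with the largest ratios. Beside these, Xist was 19.2 and 14.6, a log2 ratio of -0.39 (-0.58 to -0.21), Y-linked genes summed to 0.959 and 1.53 (0.67, -0.05 to 1.42), and oligodendrocyte markers to 11.7 and 7.49 (-0.64, -0.89 to -0.39). The VIP list's percentile moved to 7.98 against random lists matched on nothing and to 11.8 with members above the median level. The respiratory chain, with its 78 members above the median level, lay below the range of random lists (median -0.24, percentile 0.02).

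In Pv nuclei of the Mecp2 knockout, adhesion genes led the higher side. Cdh13, encoding the membrane-anchored T-cadherin (chromosome 8, 118283733 to 119324921), was 2.45 UMI per 10000 in wild type and 5.38 in the knockout, a log2 ratio of 1.13 (0.87 to 1.40). Sema5a, a semaphorin of axon guidance, was 0.775 and 1.69, a log2 ratio of 1.12 (0.65 to 1.61). On the lower side, next to Mecp2 itself, stood mt-Cytb (-1.09) and the retinol carrier gene Rbp4 (-1.07). The peptide genes Sst and Tac1 were also lower past the size rule, but not among the 8 lower genes with the largest ratios. Of 2648 genes, 82 were higher and 79 lower past the size rule, where counting error alone gave 18.1 and 20.4.

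Further higher genes with the largest ratios in these Pv nuclei were Dpy19l1 (1.00), the cytokine receptor gene Lifr (0.97), the cold-induced RNA-binding protein gene Rbm3 (0.90), Rpl22 (0.86), the mitochondrial kinase gene Pink1 (0.84) and the repressor gene Zbtb18 (0.81). Further lower genes were the kinase gene Nek1 (-0.97), mt-Co2 (-0.95), Dcun1d1, which acts in cullin neddylation (-0.89), the haemoglobin gene Hba-a2 (-0.86) and the amino acid transporter gene Slc1a4 (-0.86).

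Of 14 lists in Mecp2 Pv nuclei, 7 lay outside the range of random lists. Adhesion and guidance genes had 6 of 36 members higher (Cdh13, Sema5a, Unc5d, Tenm4, Epha4, Unc5c) and Slitrk4 lower at -0.62 (median 0.12, percentile 99.6). Cytosolic ribosomal proteins had 52 of 61 ratios above 0 and 5 past the size rule, Rpl22, Rpl14, Rpl18a, Rpl28 and Rpl10a (median 0.17, 0.12 to 0.25, percentile 100). Neuropeptides had 2 of 4 lower, Sst from 1.64 to 0.907 (-0.85) and Tac1 from 3.11 to 1.75 (-0.83), with a median of -0.49 (percentile 0.04). Summed SST markers, Sst among them, were 4.69 and 3.91 (-0.26, -0.50 to -0.03); without Sst and Npy the ratio was 0.17 (-0.17 to 0.50). GABA receptors had 8 of 10 ratios below 0, none past the rule (median -0.21, percentile 0.39), with Gabrb1 at -0.49 and Gabra1 at -0.19. Mitochondrially encoded genes were lower in 4 of 6 cases (median -0.64, percentile 0), and their sum was 16.3 and 10.6 (-0.63, -0.76 to -0.49). DNA methylation machinery (median -0.30, percentile 1.51) comprised 4 measured genes, of which Mecp2, the knocked-out gene, alone passed the rule. Without Mecp2 the list was within the range of random lists (median -0.18, percentile 13.7), and Dnmt3a was 1.62 and 1.22 (-0.41). Imprinted genes had a median of 0.13 (percentile 97.5), with Mirg past the rule at 0.50 and Meg3 at 0.24. PV markers (-0.07, percentile 16.6), MeCP2 partners (0.15, percentile 81.3), pan-GABAergic genes (-0.15, percentile 3.47), excitatory markers (-0.20, percentile 6.79), glutamate receptors (-0.08, percentile 14.9), channels (-0.05, percentile 17.3) and the respiratory chain (0.04, percentile 78.0) stayed within it. Summed haemoglobin transcripts were 7.41 and 4.57 (-0.70, -0.91 to -0.49) and oligodendrocyte markers 2.85 and 2.21 (-0.37, -0.68 to -0.06) in the same pools. With members above the median level, the percentiles of DNA methylation machinery (33.1), GABA receptors (3.01), neuropeptides (4.86) and imprinted genes (94.5) moved within the range of random lists.

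In Vip nuclei of the Mecp2 knockout, Cdh13 again had the largest positive ratio, 0.995 UMI per 10000 in wild type and 2.95 in the knockout, a log2 ratio of 1.57 (1.04 to 2.12). VIP-type peptide and marker genes were lower: Tac2 was 7.97 and 3.79 (-1.07, -1.37 to -0.78), Synpr, a synaptic vesicle protein gene, 16.1 and 10.8 (-0.58), and Calb2, calretinin, 2.41 and 1.65 (-0.55). Vip was 53.6 and 42.6 (-0.33) and Penk 8.81 and 6.52 (-0.43), both under the size rule. LAMP5 markers had 3 of 3 ratios above 0 (median 0.21, percentile 87.9, within the range of random lists). Whether the mix of interneuron types among nuclei called Vip differed between the genotypes was not tested, so these differences need not lie within VIP cells. Of 1272 genes, 68 were higher and 56 lower, where counting error alone gave 10.1 and 10.7. Mecp2, at a mean below 1.72, was not among the measured genes here.

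Other higher genes with the largest ratios in these Vip nuclei were Cds1 (0.98), Dkk3 (0.95), the MAP kinase kinase gene Map2k1 (0.92), the adhesion receptor gene Adgrb1 (0.90), Trp53i11 (0.89), the transcription factor gene Maf (3.31 and 6.07, 0.88) and the nuclear receptor gene Rora (0.87). The lower ones were the haemoglobin genes Hba-a2 (-1.70), Hbb-bt (-1.62) and Hbb-bs (8.97 and 3.24, -1.47), Igfbp5, an insulin-like growth factor binding protein (-1.25), Sdha, a complex II subunit (-1.12), Marcks, a protein kinase C substrate (-1.07), Tac2, and the synuclein gene Snca (-0.96).

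Of 13 lists in Mecp2 Vip nuclei, 2 lay outside the range of random lists, both below it: VIP markers, with 11 of 13 ratios below 0 and 3 lower past the rule (median -0.28, -0.38 to -0.12, percentile 0.01), and neuropeptides, with only Tac2 past it (median -0.33, percentile 0.095). The VIP marker and neuropeptide lists both hold Vip, Cck, Crh, Penk and Tac2, so their medians are not separate results. Cck (0.26), Prox1 (0.19) and Npy (20.8 and 27.4, 0.40) had positive ratios. Adhesion and guidance genes had 7 of 25 members higher (Cdh13, Ntm, Sema3e, Epha5, Epha7, Opcml and Robo2) and Cdh2 lower at -0.60, with a median of 0.12 at percentile 97.3. LAMP5 markers (0.21, percentile 87.9), with Ndnf at 0.65, imprinted genes (0.04, percentile 64.9), ribosomal proteins (0.03, percentile 77.5), the respiratory chain (0.15, percentile 92.1), mitochondrially encoded genes (-0.32, percentile 3.18), pan-GABAergic genes (0.06, percentile 74.6), excitatory markers (0.02, percentile 43.7), glutamate receptors (-0.06, percentile 27.1), GABA receptors (-0.13, percentile 7.05) and channels (-0.08, percentile 14.2) stayed within it. Haemoglobin transcripts summed to 16.1 in wild type and 5.40 in the knockout, a log2 ratio of -1.58 (-1.81 to -1.34), and astrocyte markers to 6.84 and 5.69 (-0.26, -0.53 to -0.001). Summed SST markers were 26.5 and 32.1 (0.27, 0.15 to 0.39), a rise that came from Npy, since the other 11 were 5.70 and 4.68 (-0.29). By the mean, LAMP5 markers (percentile 98.3) and adhesion genes (percentile 99.9) lay outside the range. With members above the median level, mitochondrially encoded genes did (percentile 0.89), while the adhesion list (84 genes) turned to a median of -0.061 (percentile 12.8), so its direction depended on the genes counted, as did that of the respiratory chain (77 genes, -0.11, percentile 4.83).

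**Figure D2:**
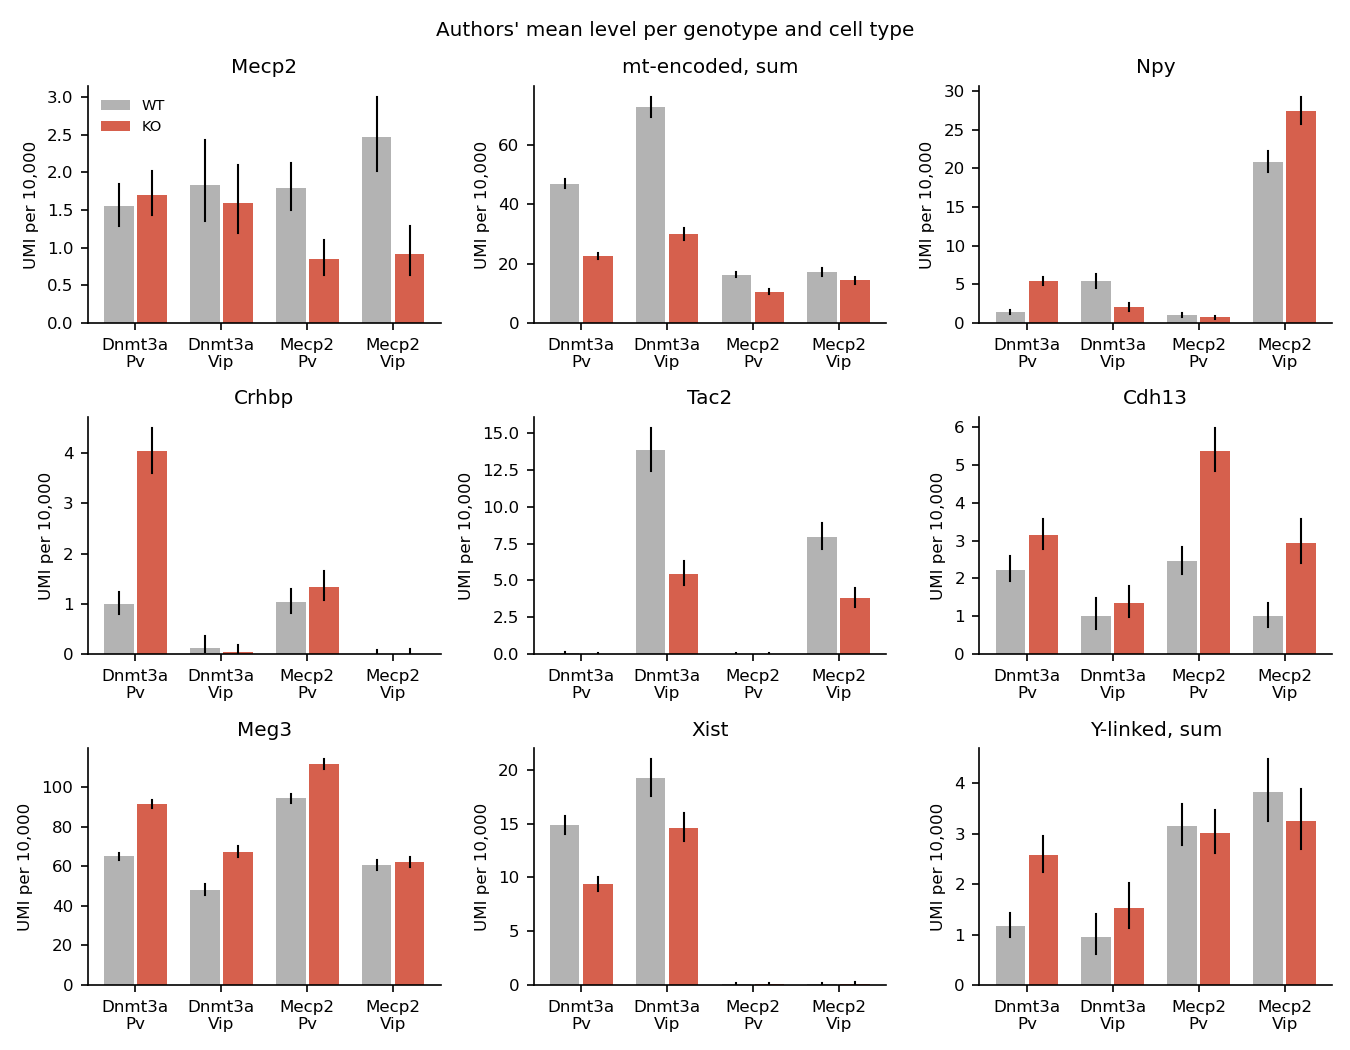
The authors' mean level in UMI per 10000 (y axis) in wild-type (grey) and knockout (red) nuclei of each table and cell type (x axis), with black lines as 95% counting intervals. Mecp2 is lower in both Mecp2 knockout pools, Crhbp is higher in Dnmt3a knockout Pv nuclei (0.992 and 4.03), and Tac2 is lower in the knockout Vip nuclei of both tables.

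Across the 4 comparisons, 20 of 54 list medians were outside the range of random lists, 8 above and 12 below. Unrelated lists of independent genes would give 2.70. Among the 12 is the DNA methylation machinery in Mecp2 Pv nuclei, which is there only with Mecp2 itself counted. The lists share members, such as Npy and Sst on the SST and neuropeptide lists. Vip, Cck, Crh, Penk and Tac2 are on both the VIP and the neuropeptide list. Genes of a list may vary together, and Pv and Vip nuclei share libraries. The excess of 20 over 2.70 is therefore not a measure against chance. Several lists had too few measured members. Germline genes, which DNA methylation silences in somatic cells, had 0 measured members in any comparison. Of the immediate-early genes only Homer1 (-0.31) and Dusp1 (0.17) were measured in Dnmt3a Pv nuclei and Homer1 (-0.10) in Mecp2 Pv nuclei. Astrocyte markers had at most 2 measured members, and microglia and vascular markers at most 1, Pecam1 (0.36 in Dnmt3a Pv nuclei). Excitatory markers (-0.20, percentile 8.73) and oligodendrocyte markers (0.17, percentile 83.9) were within the range in Dnmt3a Pv nuclei.

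Whether the Dnmt3a and Mecp2 knockouts differ from their wild types in the same genes was asked within each cell type. In Pv nuclei, 8 genes were higher in both knockouts, against 2.57 under independence: Rbm3 (0.95 for Dnmt3a and 0.90 for Mecp2), the cholesterol transporter gene Abca1 (0.86 and 0.81), the calcium-dependent kinase gene Camk2d (0.65 and 0.62), Tenm4 (0.68 and 0.62), Epha4 (0.58 and 0.61), Platr9 (0.57 and 0.61), B3gat1 and Irs2. Another 12 were lower in both, against 3.20: mt-Cytb, mt-Co2, mt-Nd1 and mt-Co1, Rbp4 (-0.82 and -1.07), the lipase gene Lpl (-0.70 and -0.78), the microtubule gene Dcx (-0.69 and -0.60), Ndufa5, Brd4, Kcnab2, Gm19938 and Hmgcs1. Tmeff1, Sst (0.54 and -0.85) and Uqcrc2 were past the size rule with opposite signs. In Vip nuclei, Epha5 (0.51 and 0.63) and the protocadherin gene Pcdh9 (0.50 and 0.70) were higher in both, 2 genes against 0.935, and 6 were lower in both against 1.66: Tac2 (-1.34 and -1.07), Igfbp5 (-0.75 and -1.25), the ion channel gene Asic4 (-0.62 and -0.94), Hbb-bs (-0.60 and -1.47), Ier3ip1 and Fez1. Hint1 and B3galt2 had opposite signs. Across genes, rho was 0.157 (r = 0.183, 2517 genes) in Pv and 0.173 (r = 0.193, 802 genes) in Vip nuclei. With all genes above the median level, rho was 0.0639 and 0.0256.

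**Figure D3:**
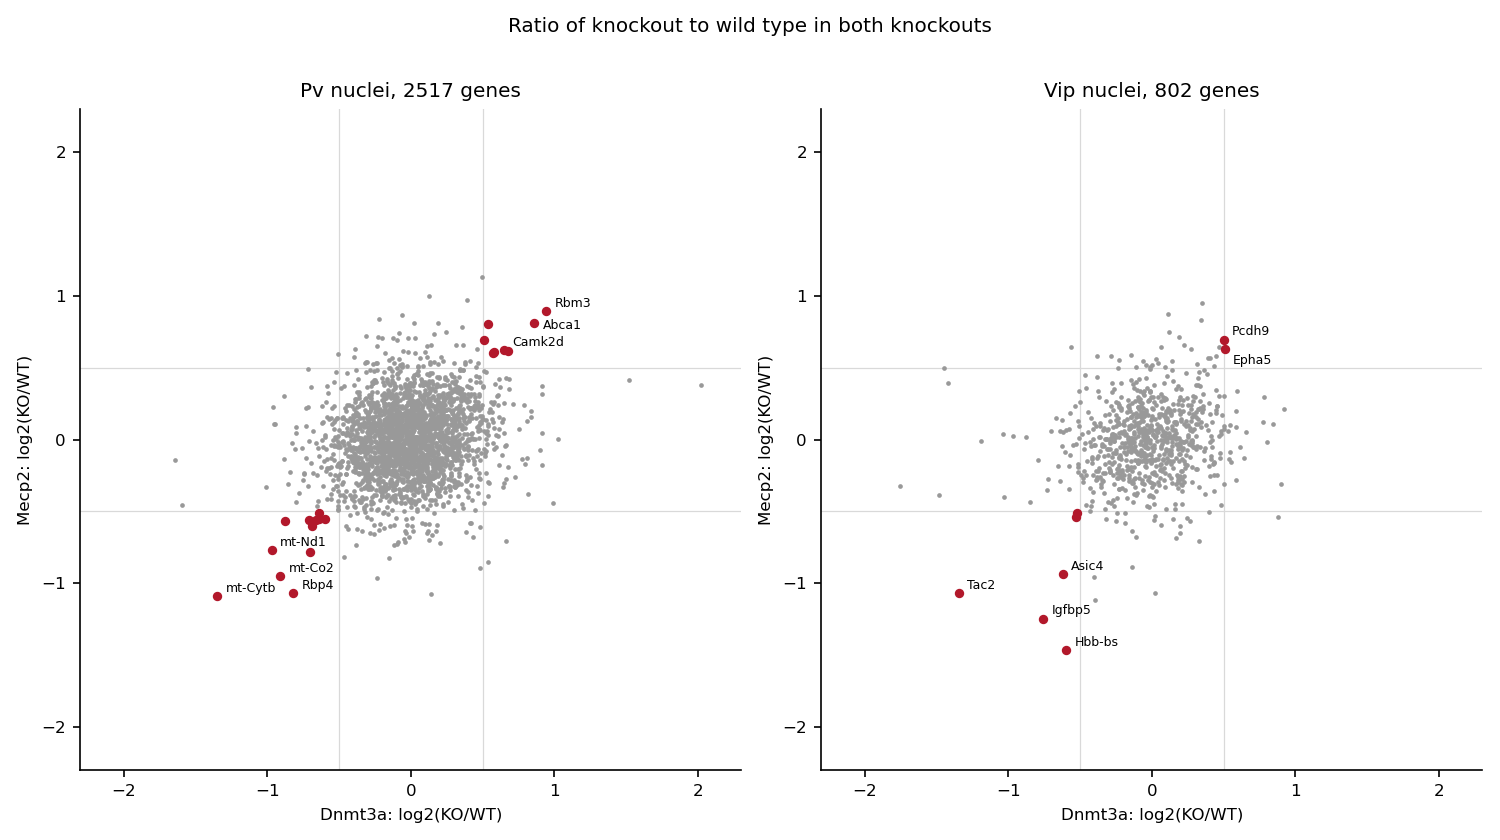
Log2 ratio of knockout to wild type for Dnmt3a (x axis) and Mecp2 (y axis), each point a gene measured in both tables, 2517 in Pv nuclei (left) and 802 in Vip nuclei (right). Red points passed a log2 ratio of 0.5 in size with the same sign in both, 8 higher and 12 lower genes in Pv nuclei and 2 and 6 in Vip nuclei, and grey lines mark that size.

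The wild types of the 2 tables, which are different nuclei, differed more from each other than knockout and wild type did within a table. The libraries of the 2 tables shared no sequencing run, so differences between these wild types cannot be told apart from differences between runs. They also differed in sex transcripts: Xist was 14.9 in the Dnmt3a and 0.0613 in the Mecp2 wild-type Pv pool, and summed Y-linked genes 1.17 and 3.16. Between the wild-type Pv pools, 319 genes were higher and 312 lower for Mecp2 littermates, 21.3% of 2967 genes, against 9.65% (Dnmt3a) and 6.08% (Mecp2) between genotypes. Between the wild-type Vip pools it was 109 and 152, or 26.9% of 969 genes, against 9.61% and 9.75%.

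Whether Pv and Vip nuclei of a knockout share their differences was asked within each table. For Dnmt3a, Rasgrf1 was higher in both, from 3.80 to 7.18 UMI per 10000 in Pv (0.92, 0.71 to 1.12) and from 4.19 to 7.93 in Vip nuclei (0.92, 0.59 to 1.25), as was Noct (0.65 and 0.84), 2 genes against 0.588 under independence. Lower in both were 14 genes against 1.25, of which 8 were the mitochondrially encoded mt-Atp6, mt-Nd4, mt-Nd2, mt-Cytb, mt-Nd1, mt-Co2, mt-Co3 and mt-Co1. The others were Fam65b (-0.62 and -0.79), Limch1 (-0.60 and -0.88), the lipoprotein receptor gene Vldlr (-0.56 and -0.65), Cox6c, Stmn2 and Atp5g3. For Mecp2, Cdh13 (1.13 and 1.57) and Camk2d (0.62 and 0.53) were higher in both, 2 genes against 1.07, and Hba-a2, Hbb-bs and the channel gene Ttyh1 (-0.64 and -0.90) were lower in both, 3 against 0.589. Rho across genes was 0.280 (r = 0.353, 810 genes) for Dnmt3a and 0.208 (r = 0.226, 1196 genes) for Mecp2. Over genes above the median level it was 0.0562 and 0.0462. Pv and Vip nuclei of a genotype came from the same libraries, so their values are not independent.

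Gene length, which has been tied to the effects of MeCP2 and of non-CG methylation, was compared with the ratios over the 97.8% to 98.4% of measured genes with an annotated length. Rho of ratio and length was 0.030 for Dnmt3a Pv, 0.040 for Dnmt3a Vip, 0.018 for Mecp2 Pv and 0.043 for Mecp2 Vip nuclei. The lowest and highest medians over 5 length bins were -0.05 in Dnmt3a Vip and 0.04 in Mecp2 Pv nuclei. Among genes over 100 kb, such as Cdh13, Sema5a and Rora, the share higher past the size rule was 5.78%, 5.29%, 4.07% and 7.62% in the same order, against 4.13%, 2.97%, 2.88% and 4.38% of shorter genes. The share lower was 4.62%, 3.70%, 2.22% and 3.49% among long genes and 5.18%, 6.56%, 3.17% and 4.48% among shorter ones. The shorter genes included the mitochondrially encoded ones, of which 8 of 8 measured were lower in each Dnmt3a comparison. In Dnmt3a Vip nuclei the lower genes were 7 long and 42 shorter ones. Shares without mitochondrially encoded genes were not taken.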

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

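The test of the sum of Uty, Kdm5d and Eif2s3y was set out before its result was seen, and the other 8 tests below were chosen after.

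Npy and Wbp5 passed the size rule with opposite signs in Pv and Vip nuclei of the Dnmt3a knockout. The log2 ratio of Npy was 1.92 (1.62 to 2.23) in Pv and -1.42 (-1.86 to -0.99) in Vip nuclei. Wbp5 was 1.40 UMI per 10000 in wild type and 2.04 in the knockout in Pv nuclei, a log2 ratio of 0.54 (0.19 to 0.90), and 2.96 and 2.04 in Vip nuclei, a log2 ratio of -0.54 (-1.03 to -0.05). With a single pooled value per genotype the difference between cell types was not tested across animals.

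Npy and Crhbp were higher together in Pv nuclei of the Dnmt3a knockout. Free RNA of SST cells in the knockout droplets is argued against by the knockout Vip nuclei of the same libraries, where Npy and Crhbp summed to 2.06 (1.59 to 2.61) UMI per 10000, below the gain in Pv nuclei of at least 6.00, and Crhbp alone stood at 0.0412 against 4.03 in Pv nuclei. A larger share of SST-type nuclei among those called Pv cannot be told apart from a difference within Pv nuclei: in Pv nuclei Sst was higher (0.54, 0.31 to 0.76), as that share would need, but the other 10 SST markers, without Npy, were not (3.20 and 2.94 summed, -0.12, -0.38 to 0.14), so the rise of all 12 (0.72) and of the 11 without Npy (0.26) came from Npy and Sst. The interval of Sst ends below that of Npy, the 10 markers are few UMI, and types of SST cell that differ in Npy were not separated. An effect of the genotype stays open and was not tested.

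Mitochondrially encoded transcripts were lower in Dnmt3a knockout nuclei of both types. In Pv nuclei, an even loss of cytoplasmic RNA is argued against as the whole cause by cytosolic ribosomal protein transcripts (median log2 ratio 0.11, 0.04 to 0.14). Those transcripts cannot show whether fewer mitochondria were carried along with the nuclei, and respiratory chain transcripts were lower (-0.29). That possibility stays open and was not tested. In Vip nuclei the ribosomal median (-0.046, -0.12 to 0.05) could not tell less cytoplasmic RNA apart from other causes. Less free RNA of other cell types is argued against as the whole cause by 48 summed markers of those types, with log2 ratios of -0.022 (-0.09 to 0.05) in Pv and -0.18 (-0.29 to -0.07) in Vip nuclei; the latter leaves room for a part. Variation between nuclear preparations cannot be told apart from other causes: the wild-type Pv pools of the 2 tables differed by a log2 ratio of -1.52 (-1.62 to -1.43; 47.0 and 16.3 UMI per 10000), more than knockout and wild type did, but also in Xist (14.9 and 0.0613) and summed Y-linked genes (1.17 and 3.16), which mark sex. The libraries of the 2 tables also shared no sequencing run. The mitochondrial sum was also lower in the Mecp2 knockout, with log2 ratios of -0.63 (-0.76 to -0.49) in Pv and -0.25 (-0.42 to -0.09) in Vip nuclei. In those Vip nuclei 2 of 5 measured members had ratios above 0. Xist stood at no more than 0.0967 in any pool of the Mecp2 table, so the lower sums there did not go with a difference in Xist. For the Dnmt3a table an effect of sex or genotype stays open and was not tested, since no values per library were analysed.

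Xist was lower and Y-linked transcripts were higher in Dnmt3a knockout nuclei. A difference of Xist alone, in cells of the same sexes, is argued against by the sum of 4 Y-linked genes in Pv nuclei, with a log2 ratio of 1.13 (0.78 to 1.50). More nuclei from males in the knockout pool may be behind it: Uty, Kdm5d and Eif2s3y summed to 0.776 and 1.43, a log2 ratio of 0.88 (0.43 to 1.35) in Pv nuclei, while in Vip nuclei the ratio of 0.11 (-0.90 to 1.14) was too imprecise to decide. Singly in Pv nuclei they were at 1.53 (0.70 to 2.43), 0.67 (-0.08 to 1.45) and 0.40 (-0.47 to 1.29). Summed X-linked genes that escape inactivation were required not to be higher. They were neither higher nor lower: -0.018 (-0.19 to 0.16) in Pv and 0.076 (-0.21 to 0.37) in Vip nuclei. An unchanged sum meets this requirement, so it does not tell more males apart from equal sexes. The labels give no sex, so differences of sex and of genotype in these pools are mixed.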

How the results depend on the processing

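The size rule of 1, the counting spread of 0.15, the pseudocount for the counts, the centring, lists without the targeted gene and the leaving out of mitochondrial, haemoglobin, Y-linked and X inactivation genes were chosen after seeing the data. No list median outside the range of random lists, targeted-gene ratio or agreement between knockouts or cell types changed sign, but the side with more genes did turn: for Dnmt3a Pv (138 higher, 156 lower) when centred (151 and 132), for Mecp2 Pv (82 and 79) with the pseudocount (64 and 70), and in further cases below. Centring, the pseudocount and the leaving out each kept all 8 counts within 1.5 times, the 4 targeted-gene ratios stayed within their counting intervals, and the 12 alternative length correlations moved by less than the 95% error of a correlation over that many genes taken as independent. Over genes above the median level (12645 genes), higher and lower genes numbered 2470 and 2078 for Dnmt3a Pv, 3541 and 3219 for Dnmt3a Vip, 2216 and 2354 for Mecp2 Pv, and 2980 and 2965 for Mecp2 Vip nuclei. Rho there was 0.0639 (Pv) and 0.0256 (Vip) between knockouts and 0.0562 (Dnmt3a) and 0.0462 (Mecp2) between cell types. By construction this filter adds genes of lower level, whose ratios carry more counting error. The numbers that counting error alone would give were not drawn under this filter. A log2 ratio of 1 left 9 and 6, 3 and 11, 2 and 3, and 1 and 7 genes in the same order, and a counting spread of 0.15 left 11 and 29, 3 and 10, 4 and 5, and 5 and 5, since fewer genes can pass.

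Percentiles of list medians moved within the range of random lists with members above the median level for DNA methylation machinery (Mecp2 Pv, 33.1), VIP markers (Dnmt3a Vip, 11.8), SST markers (Dnmt3a Pv, 88.3), GABA receptors (Dnmt3a Pv 5.68, Mecp2 Pv 3.01), neuropeptides (Dnmt3a Pv 89.7, Mecp2 Pv 4.86) and imprinted genes (Mecp2 Pv, 94.5). Against random lists matched on nothing they did so for VIP markers in Dnmt3a Vip nuclei (7.98) and imprinted genes in Mecp2 Pv nuclei (91.8). The latter also did so by the mean (96.8) and without the genes left out (97.3), and DNA methylation machinery in Mecp2 Pv nuclei without Mecp2 (13.7). In turn, lists within the range moved outside it. By the mean these were pan-GABAergic genes (Mecp2 Pv, 0.22), imprinted genes (Dnmt3a Vip, 98.7), LAMP5 markers (Mecp2 Vip, 98.3) and adhesion genes (Mecp2 Vip, 99.9). With members above the median level they were the respiratory chain (Dnmt3a Vip, 0.02), mitochondrially encoded genes (Mecp2 Vip, 0.89; 1.34 matched on nothing) and pan-GABAergic genes (Dnmt3a Vip, 98.3), whose median went from -0.06 to 0.29. With these members the medians of several lists changed sign within the range. Among them were adhesion genes in Mecp2 Vip nuclei (0.12 to -0.061, percentile 12.8), voltage-gated channels in Dnmt3a Vip nuclei (0.15 to -0.067, percentile 20.9) and excitatory markers in Mecp2 Pv nuclei (-0.20 to 0.11, percentile 82.2). For these percentiles the cause was not tested.

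Planned thresholds on adjusted or unadjusted p-values, a recomputed adjustment, leaving out replicates and a second count model were not run, since they need p-values or values per library. No paired analysis was possible because the tables give 1 pooled mean per genotype and cell type. Depth limits the Vip nuclei of the Dnmt3a table most, where 3 UMI correspond to 0.114 UMI per 10000.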

Other observations

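The values below were all picked out after the data were seen, and no explanation of them was tested.

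The Vip pools of the 2 tables differed in genes of LAMP5-type and other interneurons. Between wild types, Npy was 5.39 UMI per 10000 in the Dnmt3a table and 20.8 in the Mecp2 table, a log2 ratio of 1.95 (1.69 to 2.22). Lamp5 was 1.34 and 5.58 (2.06, 1.54 to 2.61), Ndnf, a marker of layer 1 interneurons, 0.140 and 2.0 (3.84, 2.37 to 5.85), and the GABA-synthesising enzyme Gad2 6.61 and 15.4 (1.22, 0.98 to 1.47). Vip (85.8 and 53.6) and the cannabinoid receptor gene Cnr1 (51.4 and 32.1) were lower in the Mecp2 table. In Pv nuclei, Pvalb (5.50 and 5.16) and Gad1 (22.2 and 22.4) stood at like levels, and Sst was 3.49 and 1.64.

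Haemoglobin transcripts, which encode the oxygen carrier of red blood cells, were lower in both cell types of the Mecp2 knockout: Hbb-bs was 4.37 and 2.69 in Pv nuclei (-0.70, -0.97 to -0.43) and 8.97 and 3.24 in Vip nuclei (-1.47, -1.78 to -1.17). In the Dnmt3a table Hbb-bs had a log2 ratio of 0.13 (-0.15 to 0.41) in Pv nuclei and -0.60 (-1.06 to -0.14) in Vip nuclei.

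Dlk1, an imprinted gene from the cluster that holds Meg3, was listed at 0 in wild-type Vip nuclei of the Dnmt3a table and at 2.17 UMI per 10000 in the knockout, at least 19-fold higher against the floor of 3 UMI over the pool (0.114). How many nuclei or libraries carry it is not given in the sources used here.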
